A study of Mus musculus with 12 samples.

How the data were processed

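Keratinocytes of adult mouse skin had been parted by magnetic sorting (MACS) into a fraction that carried CD34, a surface glycoprotein of the hair follicle bulge, and a fraction that did not. Per the labels, 3 isolations were made, each from a pool of 6 or more mice, and the RNA of each fraction from an isolation was hybridised to 2 Affymetrix mouse arrays. The series therefore holds 12 arrays, 6 of CD34+ and 6 of CD34- cells, from 3 RNA samples per fraction. The array titles carry numbers 1 to 6 within a fraction but do not say which arrays share an RNA.

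The deposited table gives 1 log2 value per probe set and array, made with RMA per the submitters' processing notes, with a version not given in the sources used here. The notes do not say whether all 12 arrays were normalized together, and the spread over probe sets ran from 1.92 to 2.32 between arrays. The values ran from 1.87 to 14.1 across the arrays. RMA gives no call of whether a probe set was detected, so the 3 probe sets of the Trpn control, which read 2.31 to 2.95, served as a mark of the low end of the scale. Of 45101 probe sets, 64 controls were set aside, which left 45037. GEO's platform annotation, with symbols updated through Entrez identifiers, tied 34945 probe sets to 1 gene and 932 to several, and 9160 stayed unnamed here. Each of the 18193 genes was represented by its probe set with the highest mean over the 12 arrays.

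Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05 over all genes tested), without a block and with positive values meaning higher in CD34+ cells. Errors beside group means are standard deviations over 6 arrays, and errors beside log2 fold changes are limma's standard errors. The number of arrays limits the precision. Before the data were examined, a rule was set to find the arrays that share an RNA from their correlations within a fraction. It required every array to correlate best with its partner. The rule found such partners for 4 of the 6 CD34- arrays and 2 of the 6 CD34+ arrays and so gave no accepted pairs. The 12 arrays were therefore entered as separate samples, so p-values count arrays that share RNA as separate and are too small wherever such arrays are alike. Means of arrays 1-2, 3-4 and 5-6, 3 against 3, were fitted as an alternative.

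A total of 30 gene lists with 685 members, of which 640 were tested, were fixed before the data were examined. The 4 primary lists were bulge stem cell markers (without Cd34), the RB pathway, G1/S and DNA replication, and G2/M and mitosis. Others covered skin compartments (basal keratinocyte, epidermal differentiation, upper follicle and isthmus, sebaceous gland, hair matrix and inner root sheath, outer root sheath and companion layer), signalling (WNT, BMP and TGF-beta, Notch), extracellular matrix, stress and metabolism (immediate early genes, p53 targets, cholesterol synthesis, interferon response and MHC class I, cytosolic ribosomal proteins, oxidative phosphorylation) and other cell types (dermal fibroblast, endothelial, T cell, Langerhans and myeloid, mast cell, melanocyte, smooth muscle, skeletal muscle, Schwann cell, adipocyte). Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists, and again with an estimated correlation. Under the preset correlation 18 lists passed, 7 higher and 11 lower in CD34+ cells. With an estimated correlation 0 passed and 4 had an unadjusted p under 0.05. Limma's fry, which tests each list against no change and not against the other genes, called 19, with outer root sheath and companion layer, Langerhans and myeloid, and melanocyte added to the 18 and mast cell and oxidative phosphorylation absent.

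Genes are named by a rule set before the data were examined. It takes Cd34, the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between fractions, up to 4 members of each primary list and up to 3 of each other list by size of change among those past the threshold, Rb1, Rbl1, Rbl2 and E2f1 to E2f8 whatever their result, and for each list of another cell type the 2 members with the highest mean. Among the 119 genes so named, Mbp had another probe set that passed the threshold in the opposite direction. Other probe sets of a named gene need not share its change, and some read near the low end of the scale. For Brca1, Cyp51 and Sc5d no other probe set passed over all probe sets, with 1 of Cyp51 at -0.15 (limma adjusted p = 0.647). The same held for further named genes, among them Top2a, Nusap1, Cdk2, Plk2, Elovl4, Gata6, Krt17, Fgf13, Sdhd, Dcn and Dgat2. Other probe sets of Top2a were at 0.30 (limma adjusted p = 0.139) and -0.11 (adjusted p = 0.402), and that of Plk2 at 0.62 (adjusted p = 0.333). For Ccnd2 every other probe set passed and was lower too.

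The test was checked on simulated values for the same 18193 genes and 12 arrays, with 50 genes changed at each size. It recovered 16% of the genes changed by 0.5 on the log2 scale, 88% of those changed by 1, 96% at 2 and 100% at 3, with 4.46% of calls false. When 50% of the residual variance was made common to arrays of an RNA, 38.9% of the calls from 12 separate arrays were false, against 4.55% from 6 RNA means. The 50% was chosen and not measured. In the data, arrays 1-2, 3-4 and 5-6, which the rule did not accept as pairs, had a consensus correlation over genes of -0.16. A simulated list raised by 1 was called and 0 other lists were. The genes were simulated as independent, so this check could not show false calls of lists whose members correlate. Other alternatives covered the pairing of arrays, a block by title number, centring, a further quantile normalization, the choice of probe set, a filter on dim genes, a trended and robust eBayes, and leaving out each array. Exclusion of CD34+ arrays 1, 3 and 5, fits of even-numbered or odd-numbered arrays and a block by odd or even number were added after the data were seen. Differences between fractions in array measures were tested with exact permutation tests over 924 splits. Figures were drawn with matplotlib 3.10.9.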

Results

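The measurements were log2 RMA expression values of 18193 genes on 12 Affymetrix mouse arrays, 6 of CD34+ and 6 of CD34- keratinocytes from skin. The fractions came from 3 isolations and each RNA was placed on 2 arrays, so n = 6 counts arrays and stands for 3 RNA samples. Correlations between arrays over all probe sets were 0.947 to 0.995 within a fraction and 0.933 to 0.977 between fractions. The comparison asked which genes set the CD34+ fraction, the part of the skin keratinocytes that holds the slow-cycling cells of the hair follicle bulge, apart from the remaining keratinocytes, with the RB pathway and the cell cycle as the stated interest of the study.

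The sort marker Cd34 was 121-fold higher in the CD34+ fraction, at 10.15 ± 0.55 (SD, n = 6) against 3.23 ± 0.30 on the log2 scale. The log2 fold change was 6.92 (SE 0.23, limma adjusted p = 9.78e-10), and the 6 arrays of each fraction did not overlap. The level in CD34- cells lay close to the Trpn control probe sets, which read 2.31 to 2.95, so the fold may be compressed. The array carries 1 probe set tied to Cd34. With means of arrays 1-2, 3-4 and 5-6 the adjusted p was 1.72e-05.

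After Cd34, the largest rises in CD34+ cells were those of Fgf18 (log2 fold change 5.81), a growth factor of the FGF family, Il31ra (5.74), a cytokine receptor chain, Pdzrn4 (5.68), the T-box factor Tbx1 (5.28), the imprinted gene Peg3 (5.04), Igdcc4 (5.01), Shisa2 (4.81), the LIM-homeobox factor Lhx2 (4.80) and Fam171b (4.77). The largest falls were smaller. Cd3g, a chain of the T cell receptor complex, fell by 3.29, Ctla2b by 3.00 (log2 fold change -3.00), and the leukocyte antigen Ptprc fell by 2.80. Cntn1 (-2.75), Fgf13 (-2.72), Smoc2 (-2.55), the alarmin Il33 (-2.50), Cytip (-2.48), the decoy receptor Il1r2 (-2.45) and Ctla2a (-2.44) followed. The rule that named these genes required arrays that do not overlap between fractions, which held for 2355 of the 18193 genes (12.9%). Chance would give 0.216% for 12 separate arrays, and more where arrays that share RNA are alike.

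In total 4750 genes passed the threshold, 1454 higher and 3296 lower in CD34+ cells, so that 69.4% of the calls were lower. A change of 2-fold or more was reached by 361 of the higher and 849 of the lower genes, and a change of 4-fold or more by 108 and 50. The share of lower calls depended on the scaling, where the sources used here do not say whether the 12 arrays were normalized together, and on 3 arrays. It was 54.3% after a further quantile normalization (2099 higher, 2499 lower) and 80.8% after centring each array on its median (901 higher, 3801 lower), which moved the median log2 fold change of all genes from 0.040 to -0.062. Without CD34+ arrays 1, 3 and 5, an exclusion chosen after the data were seen, 1602 genes were higher and 1900 lower, and 2730 of the 4750 genes were called again in the same direction with 0 called in the opposite one. With means of arrays 1-2, 3-4 and 5-6, 4218 of the 4750 genes were called in the same direction among 5312. The p-values behind the 4750 calls treat arrays that share RNA as separate, which makes them too small wherever such arrays are alike.

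**Figure D1:**
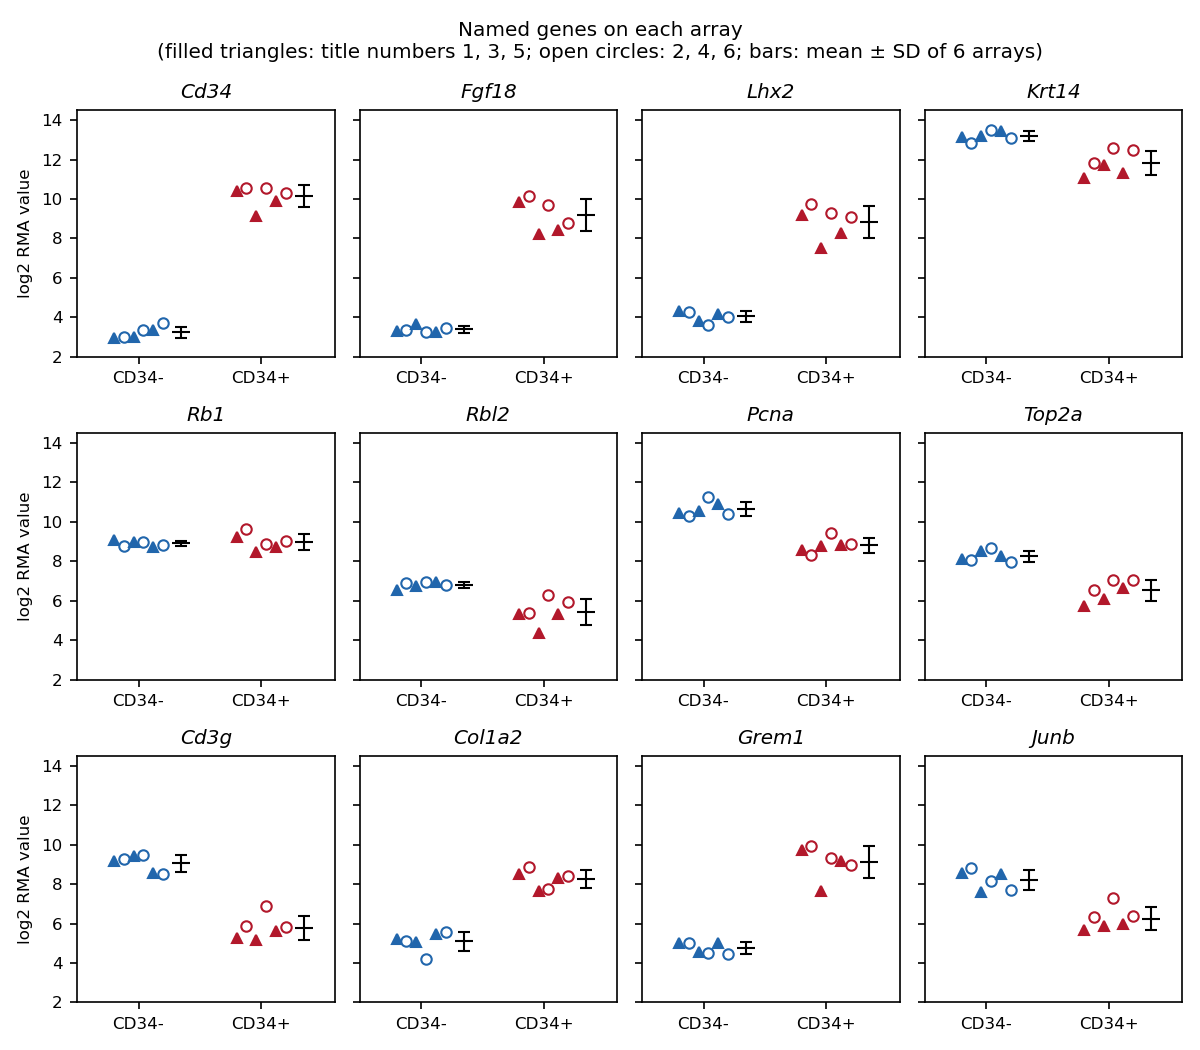
Log2 RMA values of 12 named genes on each array (vertical axis), with CD34- arrays in blue and CD34+ arrays in red, filled triangles for title numbers 1, 3 and 5, open circles for 2, 4 and 6, and bars for the mean and SD of 6 arrays. Cd34 sits near 3.23 in CD34- and 10.15 in CD34+ cells, Pcna and Top2a are lower in CD34+ cells, and Rb1 overlaps between fractions.

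Several measures of array quality moved with the fraction. The gap between the 3' and 5' control probe sets of Actb was 4.54 ± 0.66 (SD, n = 6) on the log2 scale in CD34+ and 2.48 ± 0.49 in CD34- arrays, and that of Gapdh was 4.01 ± 0.36 against 3.41 ± 0.16 (two-sided exact permutation tests, p = 0.00216 for each, the smallest that 924 splits can give). The poly-A spike-in probe sets read 10.03 ± 1.24 in CD34+ and 8.13 ± 0.26 in CD34- arrays (n = 6, exact permutation p = 0.00433). CD34+ arrays 1, 3 and 5 had a narrower spread over probe sets (SD 2.07, 1.92 and 2.02) than the other 9 arrays (2.19 to 2.32). These p-values too treat arrays that share RNA as separate.

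**Figure D2:**
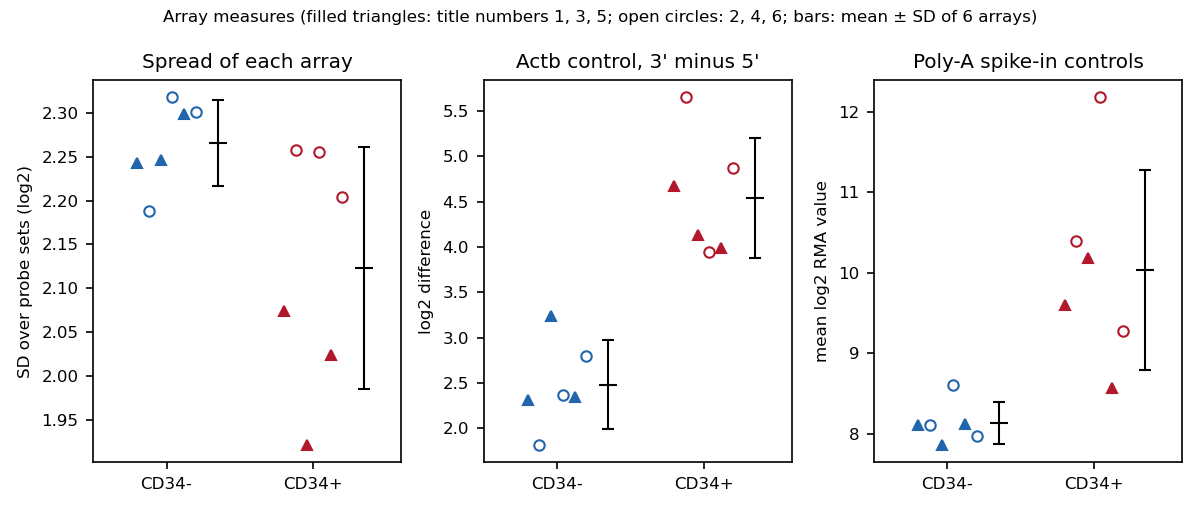
Spread over probe sets, Actb 3' minus 5' gap and poly-A spike-in level of each array (vertical axes, log2 units), with CD34- in blue, CD34+ in red, filled triangles for title numbers 1, 3 and 5, open circles for 2, 4 and 6, and bars for the mean and SD of 6 arrays. The spread is narrowest on CD34+ arrays 1, 3 and 5, at 1.92 to 2.07, and the Actb gap averages 4.54 in CD34+ and 2.48 in CD34- arrays.

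Genes known as markers of bulge stem cells were higher in the CD34+ fraction. Of 38 measured members 31 rose and 0 fell (33 and 1 adjusted over the list alone), with a median log2 fold change of 1.55. Besides Fgf18, Tbx1 and Lhx2, the keratin Krt24 rose by 4.50 (SE 0.27, adjusted p = 1.27e-07), and Lgr5 (4.18), Dkk3 (3.49), Wif1 (3.33) and Ltbp2 (4.29), which the list shares with signalling lists, rose as well. In all, 19 of the 40 markers as fixed also stand in other lists. Krt15, a keratin often used to mark the bulge and looked up after its value was seen, did not pass over all genes (-0.29, adjusted p = 0.106). It was the 1 member that fell when adjusted over the list alone. The camera test gave an adjusted p of 3.85e-24 with the preset correlation and an adjusted p of 0.225 with an estimated correlation. In the fibroblast list, 8 of 14 markers were higher in the same fraction.

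Cell cycle genes were lower in CD34+ cells. Of 44 genes of G2 phase and mitosis, 41 fell and 0 rose (42 and 0 adjusted over the list alone), with a median of -1.29. Examples are the spindle protein Nusap1 (-2.07), the cytokinesis regulator Ect2 (-1.78), the topoisomerase Top2a (8.26 ± 0.28 in CD34- against 6.52 ± 0.53 in CD34+ arrays, SD, n = 6, log2 fold change -1.74, limma adjusted p = 9.35e-05) and Ube2c (-1.70). Other probe sets of Top2a and Nusap1 did not pass. The G2/M list had an adjusted p of 5.46e-24, and an adjusted p of 0.225 with an estimated correlation. Of 42 genes of the G1/S transition and DNA replication, 24 fell and 0 rose (27 and 0 adjusted over the list alone), with a median of -0.86, among them the polymerase clamp Pcna (-1.84), thymidine kinase Tk1 (-1.81), the uracil glycosylase Ung (-1.64) and Brca1 (-1.62). That list had an adjusted p of 6.08e-10, and an adjusted p of 0.460 with an estimated correlation. The medians were -1.06 and -0.66 without CD34+ arrays 1, 3 and 5. The T cell list, with a median of -1.81, was lower in the same fraction.

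Within the RB pathway, Rb1 itself did not pass the test (8.99 ± 0.40 in CD34+ and 8.90 ± 0.14 in CD34- arrays, SD, n = 6, log2 fold change 0.087, limma adjusted p = 0.705), and its difference was -0.015 after median centring. The related pocket proteins Rbl1 (-0.92, adjusted p = 0.00967) and Rbl2 (-1.38, adjusted p = 0.00109) were lower, although Rbl1 did not pass without CD34+ arrays 1, 3 and 5 (-0.54, adjusted p = 0.136). With 12 arrays another probe set of Rbl1 was at -1.24 (adjusted p = 0.000267 over all probe sets), and its remaining ones did not pass. Of 35 members 17 fell and 2 rose (19 and 2 adjusted over the list alone), with a median of -0.43. Falls included cyclin E2, Ccne2 (-1.76), cyclin D2, Ccnd2 (-1.19), and the kinase Cdk2 (-1.17), which drive passage from G1 into S phase. Ccnd2, by the probe set used, did not pass without CD34+ arrays 1, 3 and 5 (-0.81, adjusted p = 0.0560). Its other probe sets were at -1.27 to -3.31 with 12 arrays. Of the E2F family, E2f7 (-1.05) and E2f8 (-0.46, adjusted p = 0.0220) fell, both of them repressors. E2f8 did not pass with means of arrays 1-2, 3-4 and 5-6 (adjusted p = 0.0774), nor without CD34- array 3 (adjusted p = 0.0515) or CD34- array 4 (adjusted p = 0.0559). E2f1 (-0.37), E2f2 (-0.29), E2f3 (-0.34), E2f4 (0.16), E2f5 (0.22) and E2f6 (-0.52) did not pass with 12 arrays by the probe sets used. Another probe set of E2f2 was at -0.43 (adjusted p = 0.0369 over all probe sets). E2f3 passed without CD34+ arrays 1, 3 and 5 (-0.64, adjusted p = 0.0164) and without CD34+ array 3 alone (adjusted p = 0.0419), E2f1 without CD34+ array 4 (adjusted p = 0.0315), and E2f6 on leaving out any of 4 single arrays (adjusted p 0.0148 to 0.0484). The 2 rises, of the cyclin-dependent kinase inhibitor Cdkn1c (0.54) and the DREAM complex subunit Lin52 (0.48), were looked up after their values were seen. The list had an adjusted p of 0.000387, and an adjusted p of 0.460 with an estimated correlation. Leaving out CD34+ arrays 1, 3 and 5, 10 members fell and 2 rose, with a median of -0.29.

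**Figure D3:**
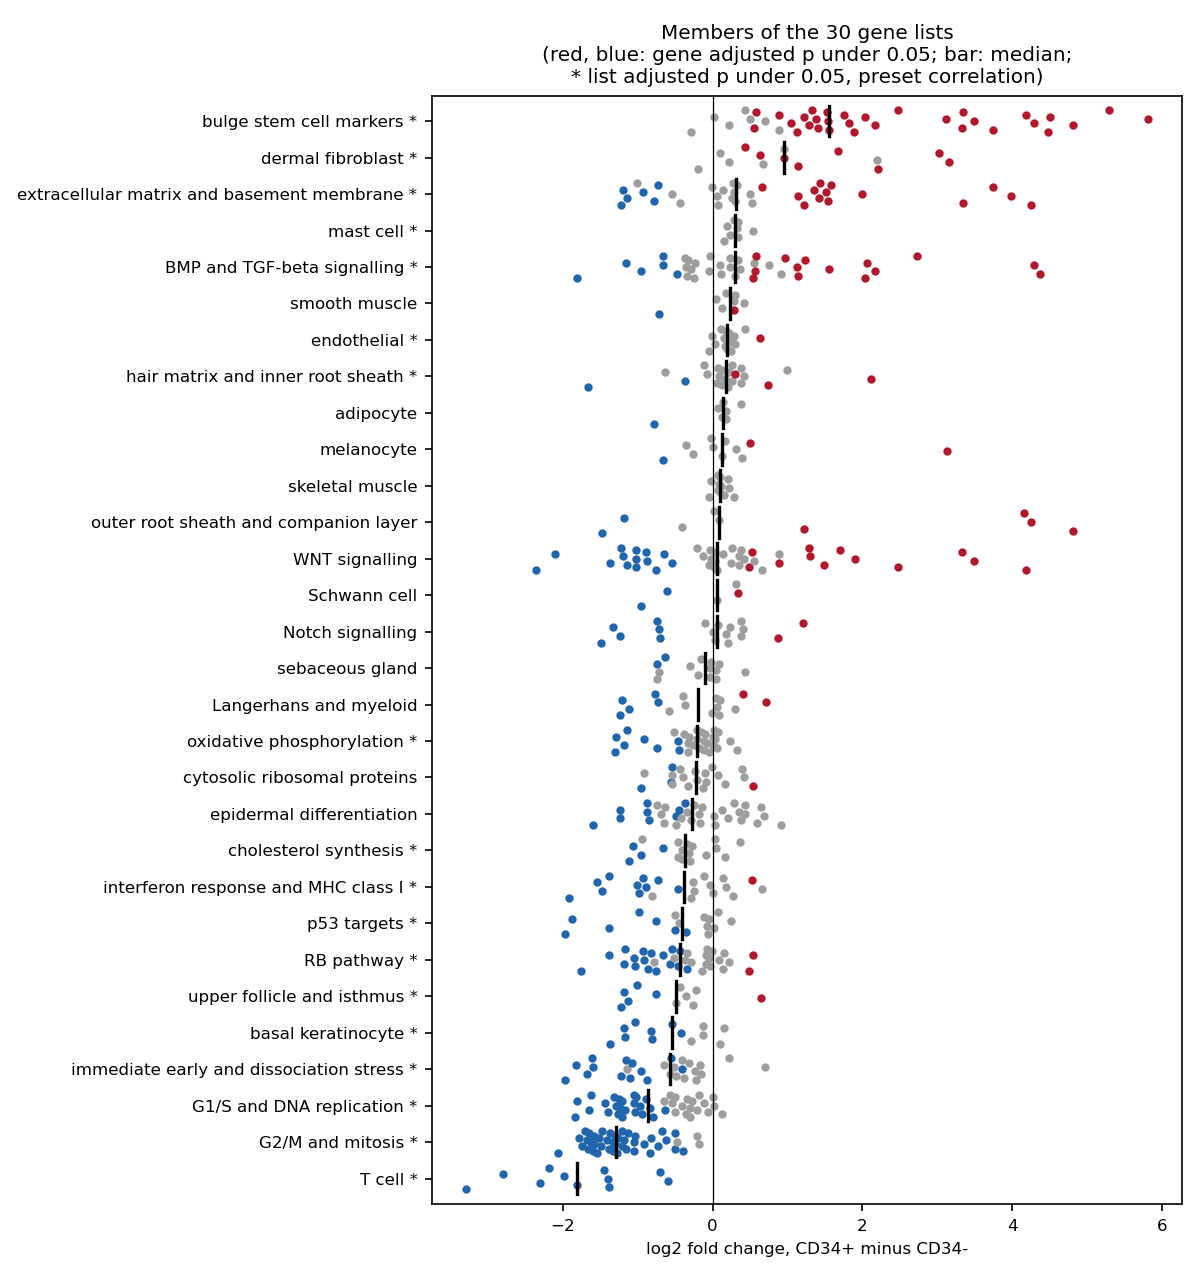
Log2 fold change, CD34+ minus CD34- (horizontal axis), of each measured member of the 30 gene lists (1 line per list, ordered by median), with members past the threshold in red (higher) or blue (lower), others in grey, and a black bar at the list median. An asterisk marks lists with an adjusted p under 0.05 at the preset correlation. The T cell, G2/M and G1/S lists lie lowest, with medians of -1.81, -1.29 and -0.86, and the bulge list lies highest, at 1.55.

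Among the compartments of the skin, basal keratinocyte genes were lower in CD34+ cells, with 8 of 13 members lower and 0 higher (the same counts adjusted over the list alone) and a median of -0.54. Krt14 (-1.37), Itgb4 (-1.18) and Itgb1 (-1.16) fell. The list's adjusted p was 0.00415, was 0.460 with an estimated correlation, and was 0.0855 without CD34+ arrays 1, 3 and 5, where Itgb4 (adjusted p = 0.0998) and Itgb1 (adjusted p = 0.134) did not pass either. Of 11 genes of the upper follicle and isthmus 5 fell and 1 rose (5 and 1 adjusted over the list alone), with Krt79 (-1.22), Krt17 (-1.18) and Gata6 (-1.12) lower. That list's median was -0.48, and its adjusted p was 0.0152, was 0.495 with an estimated correlation, and was 0.314 without the 3 arrays. Krt17 did not pass without the 3 arrays (adjusted p = 0.219), nor without CD34- array 1 (adjusted p = 0.0501) or CD34- array 5 (adjusted p = 0.0552). The companion layer keratins Krt6a (4.25) and Krt75 (4.16) rose. Their list, outer root sheath and companion layer, had 4 higher and 2 lower of 9 members, the same counts adjusted over the list alone, and did not pass as a list (adjusted p = 0.108). It passed without CD34+ array 3 (adjusted p = 0.0440) or CD34- array 5 (adjusted p = 0.0476) and on even-numbered arrays (adjusted p = 0.0344). Hair matrix and inner root sheath genes had 3 higher and 2 lower of 22 (2 and 1 adjusted over the list alone), with Hoxc13 (2.11) and Msx1 (0.74) higher and Gata3 (-1.66) lower. This list had an adjusted p of 0.0483, which was 0.460 with an estimated correlation and 0.547 without the 3 arrays, and it was lost on leaving out any of CD34+ arrays 1, 3 and 5 and CD34- arrays 4 and 6. Epidermal differentiation genes had 9 lower and 0 higher of 34 (12 and 2 adjusted over the list alone), among them Elovl4 (-1.59), Sprr1a (-1.24) and Krt77 (-1.23), with an adjusted p of 0.108. It passed without CD34+ array 6 (adjusted p = 0.0250) or CD34- array 3 (adjusted p = 0.0232). Of 14 sebaceous gland genes 2 fell and 0 rose, the same counts adjusted over the list alone, Scd1 (-0.74) and Dgat2 (-0.64), neither of which passed without the 3 arrays (adjusted p = 0.0842 and 0.0846), and the list did not pass (adjusted p = 0.310). These p-values, too, treat arrays that share RNA as separate.

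Genes of the extracellular matrix and of signalling moved in both directions. Of 34 matrix and basement membrane genes 14 rose and 6 fell (16 and 8 adjusted over the list alone), with the collagen VI chains Col6a1 (4.25) and Col6a2 (3.98) and the proteoglycan Aspn (3.75) among the largest rises. Aspn read 2.56 in CD34- arrays, within the range of the Trpn controls, so its rise is a lower bound. The list's median was 0.31, its adjusted p 0.000549, and its adjusted p with an estimated correlation 0.460. Dermal fibroblast markers had 8 higher and 0 lower of 14 (9 and 0 adjusted over the list alone), led by Col1a2 (3.15), Col5a2 (3.02) and Dcn (2.21), with an adjusted p of 4.01e-05, and of 0.278 with an estimated correlation. The fibroblast median without CD34+ arrays 1, 3 and 5 went from 0.95 to 0.34, 5 markers were higher, and the list still passed (adjusted p = 0.00407). On even-numbered arrays of both fractions the median was 0.54 (adjusted p = 0.000665). The fibroblast markers with the highest means did not pass, Vim at 0.68 (adjusted p = 0.580), which was -1.26 without the 3 arrays, and Mmp2 at -0.20 (adjusted p = 0.501), which was 0.12 after a further quantile normalization. Of 39 genes of BMP and TGF-beta signalling 14 rose and 6 fell (17 and 8 adjusted over the list alone), with the BMP antagonist Grem1 (4.37), the latent TGF-beta binding protein Ltbp2 (4.29) and Fstl1 (2.73) highest. That list's median was 0.30, its adjusted p 0.0133, and its adjusted p with an estimated correlation 0.460. WNT signalling had 12 higher and 14 lower of 45 (16 and 14 adjusted over the list alone) and did not pass as a list (adjusted p = 0.360). Of its members, Lgr5 (4.18), a receptor for R-spondins, rose, as did Dkk3 (3.49), a secreted protein of the Dickkopf family. The secreted inhibitor Wif1 rose too (3.33, from a CD34- level of 2.73 within the Trpn range). The largest falls, looked up after their values were seen, were those of Wnt5a (-2.35), Wnt3 (-2.11) and Wnt10a (-1.37).

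Of the lists of immune cells, the T cell list was lower in the CD34+ fraction. All 11 measured T cell genes fell, also when adjusted over the list alone, with Cd3g at 9.07 ± 0.44 in CD34- against 5.78 ± 0.62 in CD34+ arrays (SD, n = 6) and Ptprc (-2.80) and Trat1 (-2.30) among them. The list's median was -1.81, its adjusted p 6.08e-10, and its adjusted p with an estimated correlation 0.225. Langerhans and myeloid genes had 5 lower and 2 higher of 16 (6 and 2 adjusted over the list alone), with the MHC class II gene H2-Ab1 (-1.23), Fcer1g (-1.21) and the Langerhans cell lectin Cd207 (-1.11) lower, and did not pass as a list (adjusted p = 0.199). Its members with the highest means were H2-Aa (-0.58, adjusted p = 0.0616) and H2-Eb1, which fell by 0.73. H2-Aa passed on leaving out any of 4 single arrays (adjusted p 0.0338 to 0.0493), and another of its probe sets was at -1.52 (adjusted p = 0.000483 over all probe sets). Among endothelial genes Ramp2 rose by 0.64 and 15 of 16 did not pass, also when adjusted over the list alone, and Eng (0.24) and Kdr (0.11) had the highest means. The endothelial list had a median of 0.20 and an adjusted p of 0.0152, which was 0.460 with an estimated correlation and 0.458 without CD34+ arrays 1, 3 and 5. Of 8 mast cell genes 0 passed, also when adjusted over the list alone, with Hdc (0.54) and Gata2 (0.34) highest in mean level. With means of arrays 1-2, 3-4 and 5-6, 2 of the 8 were higher, Hdc among them (adjusted p = 0.0151), and Hdc also passed without CD34+ array 2 (adjusted p = 0.0398). The mast cell list had a median of 0.30 and an adjusted p of 0.0258, which was 0.514 with an estimated correlation, 0.546 without the 3 arrays and 0.0665 without CD34+ array 3. In melanocyte genes, Mitf rose by 3.13, Sox10 rose by 0.49 and Tyrp1 fell by 0.67, while Dct (-0.36) did not pass and the list did not either (2 higher and 1 lower of 11, the same counts adjusted over the list alone, adjusted p = 0.310). Sox10 and Tyrp1 each lost their call without any of several single arrays, and neither passed without CD34+ array 5 (adjusted p = 0.0752 and 0.0726) or without CD34+ arrays 1, 3 and 5 together (adjusted p = 0.196 and 0.0704). Neither passed with means of arrays 1-2, 3-4 and 5-6 (adjusted p = 0.0603 and 0.0832).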

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

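The split of the 12 arrays was tested as planned before the data were examined. The tests of array spread, 5' signal, matched random lists, T cells and fibroblasts were chosen after the results were seen.

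Among 100 of the 462 splits of the 12 arrays into 6 and 6, 1 split, the real one, called as many genes as the 4750 of the comparison. This argues against chance as the source of that count for 12 separate arrays. With 3 RNA samples per fraction it is weaker, because arrays that share RNA are not separate in such splits. The highest other split, which exchanged 1 array between fractions, called 2603, and 3 of the other splits called any gene.

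Most called genes were lower in CD34+ cells (69.4%). Whether loss of 5' signal in the CD34+ RNA is the source could not be decided. Among even-numbered arrays the Actb gap still differed by 2.49 on the log2 scale without overlap, and 53.7% of the calls were lower. A gap of that size thus went without a share as high as 69.4% there. The bounds of this test were set after the results were seen. The share also moved with the scaling of the arrays, so it is no direct measure of 5' loss. The narrower spread of CD34+ arrays 1, 3 and 5 may account for the surplus of lower calls, since without these arrays the share was 54.3%, while it was 66.7% among odd-numbered arrays. A true surplus of lower transcripts in CD34+ cells stays open, because the 3 arrays were singled out from the data.

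G2/M and G1/S genes were lower in CD34+ cells. An array effect that lowers genes by their expression level alone is argued against. Without CD34+ arrays 1, 3 and 5 the medians were -1.06 and -0.66, each below all of 10000 random lists matched on mean expression, whose lowest medians were -0.38 and -0.34. Random lists hold genes that need not move together, whereas the estimated correlations within the 2 lists were 0.470 and 0.451. The comparison therefore cannot exclude an array effect that correlated genes share. Nor does matching on level address the Actb gap, which differed between fractions without overlap also without the 3 arrays. Dividing T cells in the CD34- fraction as the whole source could not be excluded, since the G2/M list fell 0.712 times as far as the T cell list, between the bounds set for either reading. A slower cell cycle in CD34+ keratinocytes, the subject the series title names, stays open and untested.

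Dermal fibroblast genes were higher in CD34+ cells, and fibroblasts can carry CD34 and might pass a sort for it. With CD34+ arrays 1, 3 and 5 left out, 5 of the 14 markers were higher and the list still passed at the preset correlation (adjusted p = 0.00407), while Vim was at -1.26. With 12 arrays the list had an adjusted p of 0.278 with an estimated correlation. The count of 5 is too few for the reading that all rise and too many to exclude it, so the fibroblast source and matrix gene expression by the keratinocytes themselves cannot be told apart. The markers with the highest means, Vim (9.32 in CD34+ and 8.64 in CD34- arrays) and Mmp2 (8.39 and 8.59), did not pass, and 0 of the 15 markers as fixed stand in another list.

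Single arrays stood apart from the other 5 of their fraction in 12 of 312 tests, where chance gives 15.6. The gap to the nearest array, as a share of the range over 6 arrays, was 0.769 for Hoxc13 on CD34+ array 2, 0.723 for Ptprc and 0.721 for the T cell list on CD34+ array 4, 0.701 for Hes1 on CD34- array 3, 0.681 for the T cell list on CD34- array 6, and 0.677 for Eng on CD34+ array 3. It was 0.657 for the adipocyte list on CD34+ array 3, 0.647 for the Gapdh 3' minus 5' gap on CD34- array 2, 0.645 for the poly-A controls on CD34- array 4, 0.634 for Col1a2 on CD34- array 4, 0.626 for the ribosomal protein list on CD34+ array 5, and 0.6252 for E2f5 on CD34- array 2. The T cell list read 6.24 on CD34+ array 4 against 5.16 to 5.47 on the other CD34+ arrays.

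Probe sets outside the gene comparison also differed. The poly-A controls were 1.91 higher on the log2 scale in CD34+ arrays, the hybridization controls 0.756 higher, the Actb gap 2.06 larger and the Gapdh gap 0.608 larger. Of 9160 unnamed probe sets, 957 were higher and 364 lower in CD34+ cells in the limma test, against a surplus of lower calls among named genes. These counts differ in selection. Every unnamed probe set was counted, adjusted over all probe sets, while each named gene was represented by its probe set with the highest mean. Among genes above the median level 76.7% of the calls were lower.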

How the results depend on the processing

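Exclusion of CD34+ arrays 1, 3 and 5, the even-numbered and odd-numbered fits and the block by odd or even number were chosen after seeing the data, and the other alternatives before. The Cd34 difference stayed past the threshold under all 26 alternatives, at 6.72 to 7.25. Of 3046 values of the other named genes under alternatives 2837 kept their direction and their side of the threshold, as did 742 of 840 list values. Depth on arrays means signal over background, and RMA values carry no detection call, so changes of genes near the Trpn level of 2.31 to 2.95 are compressed.

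Counts moved by over 1.5 times in these cases. Testing all probe sets called 9704, 3439 higher and 6265 lower, because more were tested. A change of 2-fold or more left 1210, 361 and 849, and an adjusted p under 0.01 left 2547, 655 and 1892, as stricter thresholds must. With pairs of arrays drawn at random and averaged, the lowest of 100 draws called 2342 (663 higher, 1679 lower) and the highest 7734 (3092 higher). Median centring gave 901 higher genes. Even-numbered arrays, 3 against 3, called 1351 (626 higher, 725 lower), and odd-numbered arrays called 2346 higher. Without CD34+ arrays 1, 3 and 5, 1900 were lower. Beyond the fewer arrays and tests, the cause was not tested. Leaving out 1 array at a time called 3677 to 5957 genes.

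The number of lists called went from 18 to 11 with a further quantile normalization, to 11 among genes above the median level, to 10 without CD34+ arrays 1, 3 and 5, and to 0 with an estimated correlation. There the bulge list (1.55) had an adjusted p of 0.225, the RB pathway (-0.43) 0.460, G1/S (-0.86) 0.460 and G2/M (-1.29) 0.225, since the estimated correlations of 0.431, 0.167, 0.451 and 0.470 are far above the preset. The 10 lists called without the 3 arrays were all among the 18, in the same direction.

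The title numbers were not taken to pair arrays across fractions, since the labels tie no number to an isolation and not every number passed the check. Deviations of same-numbered arrays correlated at -0.17 to 0.48, above 0.1 for 4 of 6 numbers, and 4 of 6 correlated best with their own number. With the number as a replicate block 1471 genes were higher and 3527 lower, and with the block on means of 1-2, 3-4 and 5-6 1490 were higher and 3671 lower. Those pairs as a random block gave 2077 higher and 3834 lower, with a consensus correlation of -0.16. The levels of Y-linked genes, given last, go with an isolation held in 1-2, 3-4 and 5-6 of both fractions. If so, the fit on means of these pairs with the block comes nearest to the design.

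Directions reversed under an alternative for 8 genes and 8 lists, and the cause was not tested. Of these, oxidative phosphorylation had passed with 12 arrays (median -0.21, adjusted p = 0.00673) and the others had not. For lists the direction is that of the camera test and the value is the median, so the sign of the median need not change. After median centring Notch signalling was at -0.046 and Rb1 at -0.015. After quantile normalization Notch was at 0.024, skeletal muscle at -0.014 and Mmp2 at 0.12. With the mean of all probe sets Schwann cell was at 0.057, Vim at -0.069, E2f5 at -0.0031 and Rb1 at -0.053. Without probe sets that may share sequence Schwann cell was at 0.18 and Vim at -0.50. Among genes above the median level Notch was at -0.095. With CD34+ arrays 1, 3 and 5 left out Notch was at -0.044, melanocyte at -0.081, smooth muscle at -0.058, adipocyte at 0.0068, Vim at -1.26, Acta2 at -0.79, E2f5 at -0.63, E2f4 at -0.0095, Kdr at -0.081 and Mmp2 at 0.11. On even-numbered arrays Notch was at 0.0091, ribosomal proteins at 0.015, oxidative phosphorylation at 0.049, melanocyte at -0.071, smooth muscle at -0.027, adipocyte at -0.0067, Vim at -0.78, Acta2 at -0.61, E2f5 at -0.74, Kdr at -0.018 and Mmp2 at 0.066. On odd-numbered arrays Schwann cell was at 0.31 and Rb1 at -0.13. Leaving out 1 array at a time, Schwann cell ranged from 0.015 to 0.13, Notch from 0.022 to 0.10, Rb1 from -0.040 to 0.19, Mylpf from -0.11 to 0.011 and E2f5 from -0.12 to 0.58.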

Other observations

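The tests of symbol families below were chosen after the data were seen. They count genes as independent, so their p-values are too small where genes of a family move together.

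Immediate early genes, which respond within minutes to stress and growth factors, were lower in CD34+ cells, with 13 of 27 lower and 0 higher (16 and 1 adjusted over the list alone), among them Junb (-1.96), Fosb (-1.82) and Ier2 (-1.68). The list had an adjusted p of 1.13e-05, and an adjusted p of 0.460 with an estimated correlation. Its median went from -0.57 to -0.30 without CD34+ arrays 1, 3 and 5, with 8 lower and 1 higher (adjusted p = 0.00389). Of 16 p53 targets 7 fell and 0 rose (9 and 0 adjusted over the list alone), led by Pmaip1 (-1.97), Plk2 (-1.87) and Eda2r (-1.38), with an adjusted p of 0.00673, of 0.460 with an estimated correlation and of 0.149 without CD34+ arrays 1, 3 and 5. Interferon response and MHC class I genes had 10 lower and 1 higher of 22 (11 and 1 adjusted over the list alone), with the class I genes H2-D1 (-1.91) and H2-K1 (-1.54) and the immunoproteasome subunit Psmb9 (-1.47) lower. The adjusted p was 0.00415, and 0.460 with an estimated correlation. The T cell list (median -1.81), whose cells also carry class I genes, was lower in the same fraction. Of 18 genes of cholesterol synthesis 4 fell and 0 rose (9 and 0 adjusted over the list alone), among them Ebp (-1.12), Sc5d (-1.06) and Cyp51 (-0.96), with an adjusted p of 0.00907, of 0.541 with an estimated correlation and of 0.497 without the 3 arrays. Without the 3 arrays 2 of its genes were lower and 3 higher. Of 31 genes of oxidative phosphorylation 8 fell and 0 rose, the same counts adjusted over the list alone, including Atp5b (-1.31), Sdhd (-1.29) and Uqcrc1 (-1.19). That list had a median of -0.21 and an adjusted p of 0.00673, which was 0.6254 with an estimated correlation, and its median was 0.055 without the 3 arrays (adjusted p = 0.833). Cyp51 (adjusted p = 0.0564) and Uqcrc1 (adjusted p = 0.0510) did not pass without the 3 arrays. These p-values treat arrays that share RNA as separate samples.

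The remaining lists did not pass. Notch signalling had 6 lower and 2 higher of 18 (6 and 3 adjusted over the list alone), with the ligands Jag2 (-1.49) and Dll1 (-1.33) and the target Hes1 (-1.24) lower, and its median of 0.056 and mean of -0.13 differed in sign (adjusted p = 0.910). Cytosolic ribosomal proteins had 3 lower and 1 higher of 20, the same counts adjusted over the list alone, with Rps19 (-0.96), Rpl6 (-0.55) and Rps6 (-0.54) lower (list adjusted p = 0.173), and without CD34+ arrays 1, 3 and 5 neither Rpl6 (-0.34, adjusted p = 0.156) nor Rps6 (-0.22, adjusted p = 0.221) passed. Rps6 also did not pass without CD34+ array 5 alone (adjusted p = 0.0652). Smooth muscle genes had 1 higher and 1 lower of 8, the same counts adjusted over the list alone (adjusted p = 0.324), with Mylk (-0.72) lower, Myh11 (0.29, from a CD34- level of 2.77 within the range of the Trpn controls) higher and Acta2 (0.42) not past the threshold. Of 12 skeletal muscle genes 0 passed, also when adjusted over the list alone, with Mb at 0.29 and Mylpf at -0.047 (list adjusted p = 0.176). Schwann cell genes had 2 lower and 1 higher of 5, the same counts adjusted over the list alone (adjusted p = 0.786), with Egr2 (-0.96) and Mbp (-0.61) lower and Gfra3 (0.34) higher, and a median of 0.057 against a mean of -0.17. Mbp did not pass without CD34+ array 1 (adjusted p = 0.0993), nor did Gfra3 (adjusted p = 0.0971) or Myh11 (adjusted p = 0.0614), and these 3 genes did not pass without CD34+ arrays 1, 3 and 5 together (adjusted p = 0.513, 0.274 and 0.145). With means of arrays 1-2, 3-4 and 5-6 Mbp passed (adjusted p = 0.0145), while Gfra3 (adjusted p = 0.0647) and Myh11 (adjusted p = 0.0783) did not. Adipocyte genes had 1 lower and 0 higher of 7, the same counts adjusted over the list alone, which was Lpl (-0.78), with Retn at 0.38 (list adjusted p = 0.452). Retn did not pass with 12 arrays (adjusted p = 0.0570) but did with means of arrays 1-2, 3-4 and 5-6 (adjusted p = 0.0364) and without CD34+ array 2 (adjusted p = 0.0127) or CD34+ array 4 (adjusted p = 0.0323).

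Of 448 tests of families that share the start of a symbol, Frizzled receptor genes stood out among higher calls with 6 of 11, Fzd1, Fzd2, Fzd3, Fzd4, Fzd7 and Fzd9, where 0.879 were expected (Fisher's exact test, adjusted p = 0.00939), and 6 were called without CD34+ arrays 1, 3 and 5 (adjusted p = 0.0324). Fzd6, looked up after its value was seen, was lower (-0.65, limma adjusted p = 0.00137). Collagen genes had 13 of 42 higher (adjusted p = 0.00217), and 9 without the 3 arrays (adjusted p = 0.360). Genes with symbols that start with Eif, translation initiation factors and some of their regulators, had 22 of 47 lower (adjusted p = 0.00217). Mitochondrial ribosomal proteins had 30 of 76 lower (adjusted p = 0.00217). Without the 3 arrays the counts were 11 (adjusted p = 0.332) and 14 (adjusted p = 0.647). Wnt ligand genes had 8 of 19 lower (adjusted p = 0.256), and 8 without the 3 arrays (adjusted p = 0.0419), with Wnt5a (-2.35) and Wnt3 (-2.11), looked up after their values were seen, lowest. Kinesins had 13 of 37 lower (adjusted p = 0.256), and 13 without the 3 arrays (adjusted p = 0.0241). Proteasome subunits with symbols that start with Psmb had 7 of 11 lower (adjusted p = 0.0678), and 6 without the 3 arrays (adjusted p = 0.0419). Symbols that start with Ddx had 15 of 35 lower and those with Samd 5 of 10 higher (adjusted p = 0.0446 for each), against 10 (adjusted p = 0.178) and 2 (adjusted p = 1) without the 3 arrays.

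Odd-numbered and even-numbered arrays differed within the CD34+ fraction. Limma called 3202 genes between CD34+ arrays 1, 3 and 5 and CD34+ arrays 2, 4 and 6, and 0 in each of the other 9 splits of these 6 arrays into 3 and 3. In the CD34- fraction the same split called 0 genes (190 at an unadjusted p under 0.05). The odd-minus-even differences of the fractions correlated at 0.324 across genes, which are not independent replicates, and the test of the difference between fractions called 0 genes, so the split is not shown to belong to CD34+ arrays alone. If arrays 1-2, 3-4 and 5-6 share RNA, as the Y-linked levels below go with, each odd array holds the RNA of an even one. The 3202 calls would then be technical. Vim, chosen after its values were seen, read 11.25 on odd and 7.38 on even CD34+ arrays with its brightest probe set, 8.84 and 6.86 with another, and 8.54 and 8.99 with the last, so probe sets of this gene parted in size and direction. Col3a1, chosen likewise, read 8.81 and 5.50 with its brighter probe set and 3.78 and 3.36 with the other.

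The mean level of Eif2s3y, Kdm5d and Uty, genes of the Y chromosome, varied between arrays of a fraction. It was 5.94, 4.66 and 6.48 for CD34+ arrays 1-2, 3-4 and 5-6, and 5.80, 5.07 and 6.57 for the CD34- arrays of those numbers. Of the 15 ways to pair 6 arrays, 0 brought paired arrays closer than 1-2, 3-4 and 5-6 did in either fraction. In both fractions 3-4 was lowest and 5-6 highest. The Y-linked levels thus go with 1-2, 3-4 and 5-6 as the arrays of an isolation in both fractions, which the labels do not state. In the pairing by correlation, 1-2 was a pair of the best pairing in both fractions, and 1-2, 3-4 and 5-6 ranked 2 of 15 in CD34- and 10 of 15 in CD34+ arrays.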
